A study of Mus musculus with 6 samples.

How the data were processed

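RNA from mouse pancreatic islets, isolated and frozen before extraction, was sequenced by the authors in 6 libraries, 3 per genotype. Groups and replicate numbers came from the sample labels, and each column of the deposited table matched one label. Reads were aligned with HISAT2, per the submitters' processing notes. Its version, the counting tool, the genome build and the strand setting are not given in the sources used here. For that reason no genome coordinates are given, and antisense, overlapping and near-identical genes could share reads.

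The deposited signal values are gene counts that the authors divided by a size factor per library, as the values themselves show. In every library the values were whole multiples of a single step, and 100% came out as whole reads within 0.01 reads. The recovered size factors matched those that DESeq2 computes from the recovered reads to within 5.02e-12. Steps lay between 0.879 and 1.23, so a value is close to a read count. The table holds 18437 genes with 0 values at zero, so each gene in it had at least 1 read in every library. A filter of that kind leaves out genes silent in one genotype, and such genes were not analysed here. Mitochondrially encoded genes were not analysed here either. Of the symbols, 18373 (99.7%) matched GENCODE M21 or RefSeq names, which served only for names and for the neighbours of Sec16b.

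Genes with a value of at least 10 in at least 3 libraries were kept, 16042 in all, and 2395 fell below the filter. Values were tested as log2(value + 1), so fold changes understate the change of low genes. Limma 3.58.1 in R 4.3.3 fitted knockout minus wild type with a mean-variance trend, and p-values were two-sided with Benjamini-Hochberg adjustment at 0.05. The median SE of a log2 fold change was 0.199, and 0.12 for genes with a mean of 1000 or more. EdgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. DESeq2's independent filtering leaves some adjusted p-values undefined, and these were left so. For some genes, Ighm and Igkc among them, DESeq2 gave no p-value at all.

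Gene lists of cell types, pathways and complexes were fixed before the data were examined, and 32 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. The adipocyte list had 2 tested members, the erythrocyte list 4 and the mitochondrially encoded list 0, so these were not tested. Camera with an estimated correlation called 0 lists (lowest adjusted p = 0.594), where the preset one called 14. Fry, which asks whether a list's genes move one way on balance, also called 0 (lowest adjusted p = 0.663). Few genes stood in more than one list, among them Sox9, Atf3, Trpm5 and Hmox1. Shares of reads have exact 95% Clopper-Pearson intervals. A marker level is the mean log2 value of a list's tested members, compared by exact permutation.

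The genes named were set by a rule fixed beforehand. It took Sec16b, up to 10 genes per direction past the threshold, the 5 smallest p per direction where fewer than 5 passed, 13 fixed islet and ER genes (1 of them is not reported here), and the 3 smallest p of each list that passed camera. Predicted genes and similar entries were skipped among the genes of smallest p, which left out 1 gene, BC051142.

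The scripts were tested on simulated counts with the real means, depths and spread, in 5 runs of 16042 genes with 200 changed. Limma called 42 of 78905 unchanged genes, and 97.1% of genes changed 16-fold. A list of 30 genes shifted by −0.30 was called in 5 of 5 runs, and 0 of 160 unshifted lists were called. The simulation draws genes independently, so it says nothing about how camera behaves when genes move together. Replicates were compared for duplicate libraries, and the chi-square per degree of freedom ran from 53.5 to 304, far from sampling noise. Alternatives covered pseudocount, filter, scaling, variance model, tool, a replicate block, the acinar level as covariate, the acinar genes left out, an estimated correlation and leaving out each library. Chosen after seeing the data were the lymphocyte level as covariate and a fit without knockout replicates 1 and 3, which had the highest and lowest acinar share. That fit keeps only 1 knockout library, so it holds no spread within the knockout group and its calls rest on that library.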

Results

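Pancreatic islets, the hormone-secreting cell clusters of the pancreas, were profiled by RNA sequencing in male mice aged 30 weeks. The design set 3 libraries from Sec16b+/+ animals (wild type) against 3 libraries from Sec16b-/- animals (knockout). Sec16b encodes a protein of endoplasmic reticulum (ER) exit sites, where secretory cargo is packed into COPII-coated vesicles, and the comparison asked which islet transcripts differed without it. The deposited table held 18437 genes, and 16042 passed the filter on low values. The reads recovered from the table came to 22566274, 23195259 and 26806787 in wild type replicates 1, 2 and 3. In knockout replicates 1, 2 and 3 they came to 22084443, 24887766 and 22071895. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these samples.

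Sec16b transcript was lower in the knockout libraries but was still present in all 3. Its normalized value was 1655, 773 and 1786 in wild type replicates 1, 2 and 3, and 553, 433 and 750 in knockout replicates 1, 2 and 3. The means were 1405 ± 551 (SD, n = 3) and 579 ± 160 (SD, n = 3). On the log2(value + 1) scale the fold change was −1.22 (SE 0.35), or 2.33-fold lower. The lowest wild type value, 773, lay just above the highest knockout value, 750. The difference did not pass limma's test over all genes (adjusted p = 0.993). The two-sided exact permutation test of Sec16b alone gave p = 0.1, the smallest value that 3 libraries against 3 can give. Sec16a, the related gene with a role at the same sites, had a log2 fold change of −0.10 (SE 0.11, adjusted p = 0.993). The deposited values count reads over the whole gene, so they do not show which part of Sec16b the remaining reads came from.

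**Figure D1:**
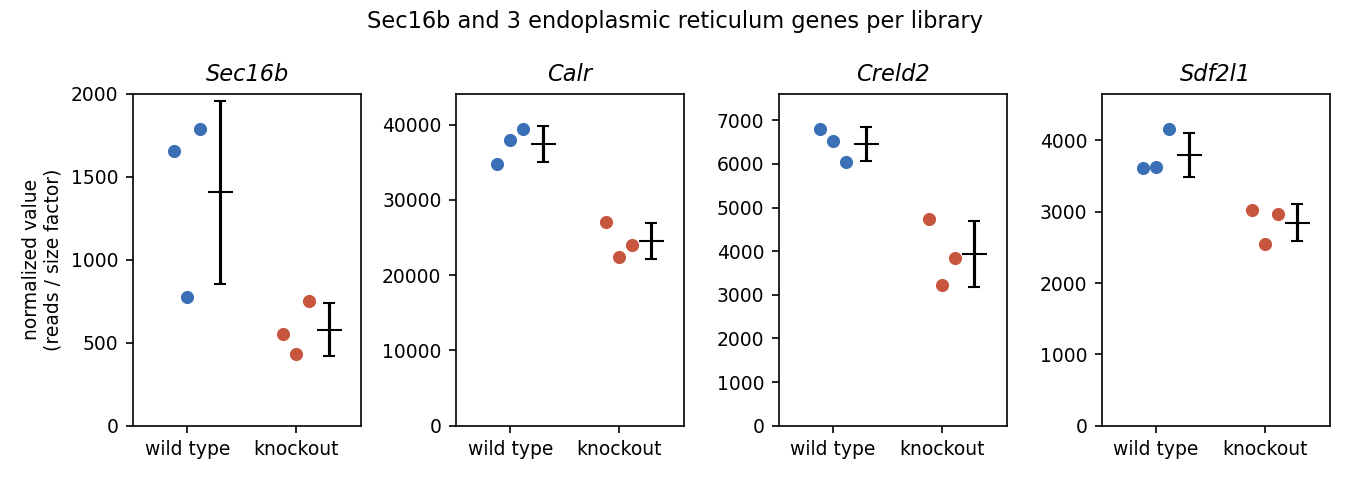
Normalized value (reads divided by a size factor, linear axis from 0) of Sec16b, Calr, Creld2 and Sdf2l1 in each library, with points for the 3 wild type and 3 knockout libraries and black bars for mean ± SD. Sec16b lay at 433 to 750 in the knockout libraries and at 773 to 1786 in the wild type libraries.

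Across the whole transcriptome, no single gene passed the threshold between knockout and wild type islets. Among the genes with the smallest unadjusted p, Pdyn, the precursor of dynorphin peptides, was at 1977 ± 129 (SD, n = 3) in wild type and 2944 ± 293 (SD, n = 3) in knockout libraries. Dusp26, a phosphatase, had a log2 fold change of 0.88 (SE 0.17) and Clip4 one of 1.03 (SE 0.22). Afm and Timp4, a plasma vitamin E carrier and a metalloproteinase inhibitor, had log2 fold changes of 2.52 (SE 0.44) and 2.47 (SE 0.45) at low levels. Afm went from 3.87 to 25.5 and Timp4 from 5.30 to 35.6. On the lower side were Galnt9, an O-glycosylation enzyme (−0.87, SE 0.16), Nbl1, a BMP antagonist (−0.59, SE 0.11), and Creld2, an ER stress-inducible protein (−0.73, SE 0.15). Gsn, the actin-severing protein gelsolin (−0.42, SE 0.09), and Atrnl1 (−0.53, SE 0.11) followed. These 10 genes were each separated between the groups in all 6 libraries, and none of them passed limma's adjustment (adjusted p = 0.993).

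Limma called 0 of 16042 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 it found 494 genes, 276 higher and 218 lower, where chance alone gives 802. The 3 knockout values lay all above or all below the 3 wild type values in 1456 genes, or 9.08%, where chance gives 10%. The quasi-likelihood test of edgeR on the recovered reads also called 0 genes, with 514 at an unadjusted p under 0.05, where chance gives 802. The Wald test of DESeq2 on the same reads called 12 genes, 6 higher and 6 lower. It had 603 genes at an unadjusted p under 0.05, where chance gives 919, and no adjusted p for 7882 genes. Its higher genes were Pdyn, Dusp26, Fosb, Clip4, Lars2 and BC051142, and its lower genes were Calr, Hsp90b1, Galnt9, Creld2, Nbl1 and Gsn. Lars2, BC051142 and Hsp90b1 are named here because DESeq2 called them, a choice made after their values were seen. The lowest DESeq2 adjusted p was 0.00711, for Calr, an ER calcium-binding chaperone at 37367 ± 2385 (SD, n = 3) in wild type and 24491 ± 2404 (SD, n = 3) in knockout libraries. The limma fit was also run on simulated data with the same depths and spread, 200 changed genes per run and genes drawn independently. It called 32.0% of genes changed 2-fold, 67.9% of those changed 4-fold and 91.3% of those changed 8-fold. The adjustment is stricter where fewer genes change, so these shares do not show which changes limma could find in the real libraries.

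Genes of the early secretory pathway were lower on average in the knockout libraries, but the levels of the 2 genotypes overlapped. Of 30 genes of the unfolded protein response and ER chaperones, 23 were lower and 7 higher, with a mean log2 fold change of −0.22. Creld2 (−0.73), Calr (−0.61, SE 0.15) and Sdf2l1, an ER cochaperone (−0.42, SE 0.11), had the smallest p. The 10 members with an unadjusted p under 0.05 were all lower, and 0 members passed either over all genes or adjusted over the list alone. Hspa5, the main ER chaperone BiP, had a log2 fold change of −0.29 (SE 0.33), at 114179 ± 30654 (SD, n = 3) in wild type and 91851 ± 16622 (SD, n = 3) in knockout libraries. Among the COPII coat and ER exit genes, 26 of 31 were lower, with a mean of −0.09, led by the cargo receptors Lman2 (−0.28, SE 0.09), Tmed9 (−0.23, SE 0.10) and Surf4 (−0.20, SE 0.11). Among the COPI coat and Golgi genes, 23 of 26 were lower, with a mean of −0.12, led by Copz1 (−0.25, SE 0.09), Kdelr2 (−0.22, SE 0.10) and Golga2 (−0.17, SE 0.08). In the camera test, the ER chaperone, COPI and COPII lists had adjusted p of 1.6e-07, 7.0e-06 and 0.00013. Each was lost with an estimated correlation (adjusted p = 0.594 for all 3). The exact permutation test of the mean log2 level per library gave p = 0.2 for each (adjusted p = 0.733). Knockout replicates 2 and 3 lay below every wild type library in all 3 lists. Knockout replicate 1 lay above wild type replicate 1 for ER chaperones (12.99 against 12.95) and COPII (11.64 against 11.62). For COPI it lay above wild type replicate 2 (11.85 against 11.84). Again 0 COPI and 0 COPII genes passed adjusted over the list alone. Without wild type replicate 3 the ER chaperone mean was −0.14 and the COPII mean −0.06 (adjusted p = 0.0537), and without knockout replicate 2 the COPI mean was −0.06.

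**Figure D2:**
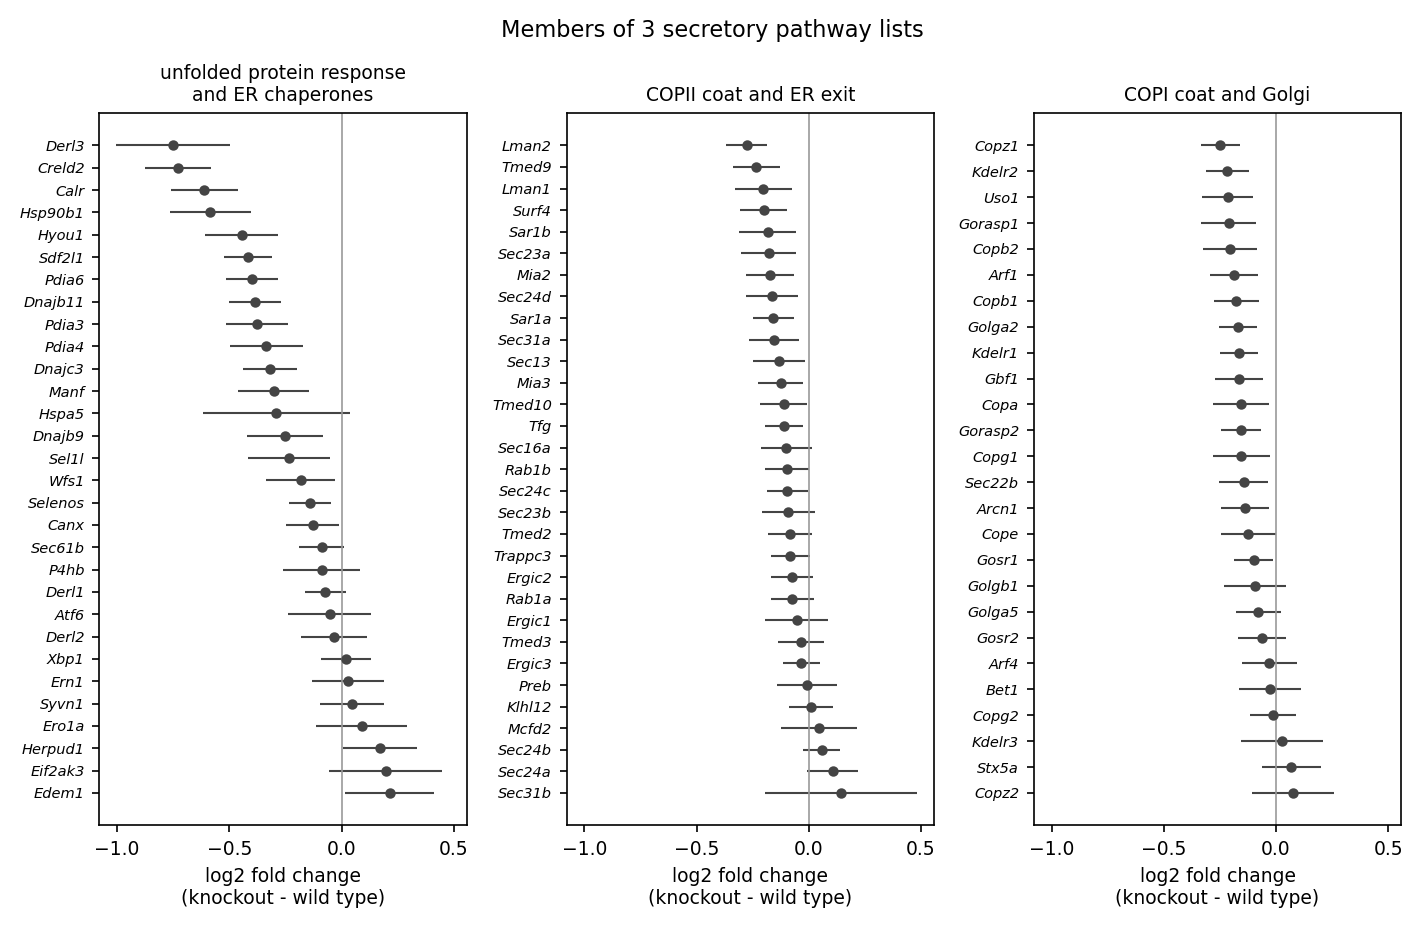
Log2 fold change of knockout against wild type (x axis) for each gene (y axis) of the unfolded protein response and ER chaperone list, the COPII coat and ER exit list, and the COPI coat and Golgi list. Points are estimates and bars are ± 1 SE, with 23 of 30, 26 of 31 and 23 of 26 genes below 0.

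Genes of the integrated stress response, the pathway of Atf4 and Chop, did not pass as a group with all 6 libraries. Of 26 genes, 14 were lower and 12 higher, with a mean of 0.10, a median of −0.02 and a camera adjusted p of 0.664. Ddit3, which encodes Chop, had a log2 fold change of 0.12 (SE 0.14). The list passed in 5 of 23 alternatives, with means from −0.19 without knockout replicate 1 to 0.27 without wild type replicate 1. The 34 exocytosis and secretory granule genes had a mean of −0.06 (camera adjusted p = 0.386), and they passed in 3 of 23 alternatives. These included array weights (−0.10, adjusted p = 0.0401) and the fit without knockout replicate 3 (−0.11, adjusted p = 0.0157). The remaining one was the fit without knockout replicates 1 and 3 (−0.16), which left 1 knockout library. Without knockout replicate 2 the mean nearly vanished. The 31 ion channel and signalling genes of stimulus-secretion coupling had a mean of 0.04 (camera adjusted p = 0.642). They passed in 2 of 23 alternatives, without knockout replicate 1 (0.11, adjusted p = 0.0369) and with the lymphocyte covariate (0.12, adjusted p = 0.0409). Their mean turned negative without wild type replicate 1.

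The list of beta cell genes did not pass with all 6 libraries. Its 29 genes of beta cell identity and insulin processing had a mean log2 fold change of −0.02, with 17 lower and 12 higher (camera adjusted p = 0.664). It passed without knockout replicate 3 (mean −0.16, adjusted p = 0.00265), and its mean ran from −0.16 to 0.07 with single libraries left out. Without knockout replicates 1 and 3, which left 1 knockout library, the mean was −0.11. Ins1 was at 615172 ± 126527 (SD, n = 3) in wild type and 562768 ± 100154 (SD, n = 3) in knockout libraries, a log2 fold change of −0.12. Ins2, a close copy of Ins1 whose reads the counting could have shared, had −0.11, and Iapp, the amyloid peptide released with insulin, −0.14. Limma's SE of 0.77, 1.74 and 0.46 for these 3 came mostly from its variance trend at the top of the expression range. The SE from each gene's own spread was 0.22 for Ins1, 0.20 for Ins2 and 0.14 for Iapp. The transcription factors Pdx1 and Mafa had −0.26 (SE 0.16) and −0.06 (SE 0.40). The glucose transporter gene Slc2a2 had −0.38 (SE 0.37).

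Genes of the other islet endocrine cells were higher as groups. The 12 genes of delta, PP and epsilon cells had a mean log2 fold change of 0.32, with 10 higher. The peptide hormone genes Pyy and Ppy had 0.61 (SE 0.20) and 0.44 (SE 0.18), Lepr, the leptin receptor gene, 1.26 (SE 0.50), and Sst, the somatostatin gene, 0.20 (SE 0.20). The 14 alpha cell genes had a mean of 0.29, with 12 higher. Gcg, the glucagon gene, had 0.67 (SE 0.62), Dpp10 0.49 (SE 0.18) and Ttr 0.48 (SE 0.31), while Gc, a vitamin D carrier, was on the lower side at −0.56 (SE 0.16). Camera gave adjusted p of 0.00323 for the delta, PP and epsilon list and 0.0396 for the alpha list, and both were lost with an estimated correlation (adjusted p = 0.594 for each). No member of either list passed adjusted over the list alone, where the count was 0. The alpha list also lost its call without wild type replicate 1 (0.24), wild type replicate 3 (0.22) or knockout replicate 2 (0.15), and with no filter on low values (adjusted p = 0.0672), and its mean was 0.44 without knockout replicate 3. The delta, PP and epsilon list lost its call with the lymphocyte level as covariate (0.23, adjusted p = 0.0555). The 21 genes normally kept low in beta cells or expressed on dedifferentiation had a mean of 0.28 (camera adjusted p = 0.0396, adjusted p = 0.857 with an estimated correlation). Among them Sox9 had 1.03 (SE 0.49), Myc 0.51 (SE 0.26) and Igfbp4 1.09 (SE 0.58). The call was lost without knockout replicate 1 (mean −0.00060), knockout replicate 2 (0.23) or wild type replicate 3 (0.05), and the mean was 0.45 without wild type replicate 1 and 0.62 without knockout replicate 3. It was also lost with the acinar level as covariate (0.10, adjusted p = 0.476), with the lymphocyte level as covariate (0.0049, adjusted p = 0.963) and with no filter on low values (adjusted p = 0.0992).

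Immediate early and inflammatory genes were higher on average in the knockout libraries, but not in every one. By mean log2 level, knockout replicates 1 and 2 lay above every wild type library in both lists. Knockout replicate 3 had an immediate early level of 9.70, below wild type replicate 1 (10.1). Its inflammatory level of 8.20 was below wild type replicates 1 (8.55) and 2 (8.83). Of 28 immediate early and heat shock genes, which respond within minutes to stimuli including tissue handling, 25 were higher, with a mean log2 fold change of 0.67. The AP-1 genes Fosb, Fosl2 and Junb had 1.48 (SE 0.42), 0.63 (SE 0.18) and 0.92 (SE 0.30). All 25 genes of inflammatory cytokines and chemokines were higher, with a mean of 0.81. Cxcl1, a neutrophil attractant, had 2.01 (SE 0.89), Socs3, a cytokine signalling inhibitor, 0.98 (SE 0.40), and Il1b 0.88 (SE 0.37). The 36 interferon response genes had a mean of 0.40, with 34 higher, led by Mx2 (1.19, SE 0.54), Irf1 (0.63, SE 0.34) and Stat2 (0.80, SE 0.45). In camera the adjusted p was 4.4e-10, 1.7e-06 and 0.00071 for the 3 lists. All were lost with an estimated correlation (adjusted p = 0.594, 0.594 and 0.857), and the count adjusted over the list alone was 0 in each. The exact permutation test of the mean log2 level per library gave p = 0.2, 0.3 and 0.6 in the same order. The immediate early mean was 0.36 without knockout replicate 1 and 1.05 without knockout replicate 3. The inflammatory mean was 0.38 without wild type replicate 3, 0.45 without knockout replicate 1 and 1.24 without knockout replicate 3. The interferon mean was −0.06 without knockout replicate 1 and 0.01 without wild type replicate 3, where its call was lost, and 0.75 without wild type replicate 2 and 0.71 without knockout replicate 3. The interferon call was also lost with the lymphocyte covariate (0.25) and with array weights (0.25). So it was without knockout replicates 1 and 3 (0.11), where 1 knockout library was left.

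Cells from outside the islet were present in very different amounts. The acinar list, digestive enzyme genes of the exocrine pancreas, took 5.91%, 1.30% and 3.64% of reads in wild type replicates 1, 2 and 3. In knockout replicates 1, 2 and 3 it took 18.0%, 8.63% and 0.803%. Every exact 95% Clopper-Pearson interval, which covers counting error only, was narrower than 0.1 percentage points. The insulin genes took 9.96%, 10.5% and 13.3% of wild type reads and 8.27%, 8.79% and 13.0% of knockout reads. The 33 acinar genes had a mean log2 fold change of 0.83, led by Prss3 (2.23, SE 1.73), Ptf1a (1.28, SE 1.20) and Cela3a (1.18, SE 1.14). Camera gave an adjusted p of 0.00323 (adjusted p = 0.857 with an estimated correlation), and the call was lost without knockout replicate 1 (mean −0.13), knockout replicate 2 (0.43) or wild type replicate 2 (0.23). The mean was 1.27 without wild type replicate 1, 2.18 without knockout replicate 3 and −0.17 with the lymphocyte covariate, where the call was lost. Trypsin and elastase genes have near-identical copies, so single values are uncertain. The 11 lymphocyte genes had a mean of 1.90 (camera adjusted p = 0.00488, adjusted p = 0.857 with an estimated correlation), with Ighm at 4.61 (SE 1.97), Igkc at 3.74 (SE 1.88) and Cd3g at 1.65 (SE 1.28). That call was lost without wild type replicate 2 (0.85), wild type replicate 3 (1.23) or knockout replicate 1 (1.32), with DESeq2 (0.25), with the acinar covariate (1.24) and without knockout replicates 1 and 3 (1.72), and the mean was 3.62 without wild type replicate 1. Their level differed 46.3-fold between the libraries of lowest and highest level, and the acinar level 24.5-fold. The lymphocyte mean log2 level was 9.51, 3.98 and 4.74 in wild type and 9.14, 8.13 and 6.66 in knockout replicates 1, 2 and 3. Knockout replicate 1, with the highest acinar share, also had the highest immediate early level (11.1), inflammatory level (9.78) and interferon level (11.1).

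The 18 endothelial genes had a mean log2 fold change of 0.31, with 17 higher, including Egfl7 (0.63, SE 0.18), Vwf (0.75, SE 0.31) and Robo4 (0.42, SE 0.21). Camera gave an adjusted p of 1.9e-06, lost with an estimated correlation (adjusted p = 0.594). Lists for duct cells (mean 0.31, adjusted p = 0.175), macrophages and dendritic cells (0.19, adjusted p = 0.207), stellate cells and fibroblasts (−0.25, adjusted p = 0.346) and Schwann cells and neurons (−0.39, adjusted p = 0.664) did not pass camera with all 6 libraries. Of these, the duct list passed in 2 of 23 alternatives, the macrophage and dendritic list in 3, the stellate list in 4 and the Schwann cell and neuron list in 0. With single libraries left out, the duct mean ran from 0.11 (without knockout replicate 1) to 0.50 (without wild type replicate 2, adjusted p = 0.00406), and the list also passed without knockout replicate 3 (0.48). The macrophage and dendritic mean ran from −0.18 (without knockout replicate 1) to 0.65 (without knockout replicate 3, adjusted p = 0.00026). The stellate mean ran from −0.74 (without wild type replicate 1, adjusted p = 5.6e-05) to 0.15 (without knockout replicate 3), and the list also passed without knockout replicate 1 (−0.43) or 2 (−0.49). The Schwann cell and neuron mean ran from −0.50 (without knockout replicate 1) to −0.10 (without wild type replicate 1). The marker level of each cell type was compared by an exact two-sided permutation test, and 0.1 was the smallest p, for the endothelial and the delta, PP and epsilon lists (0.733 after adjustment).

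**Figure D3:**
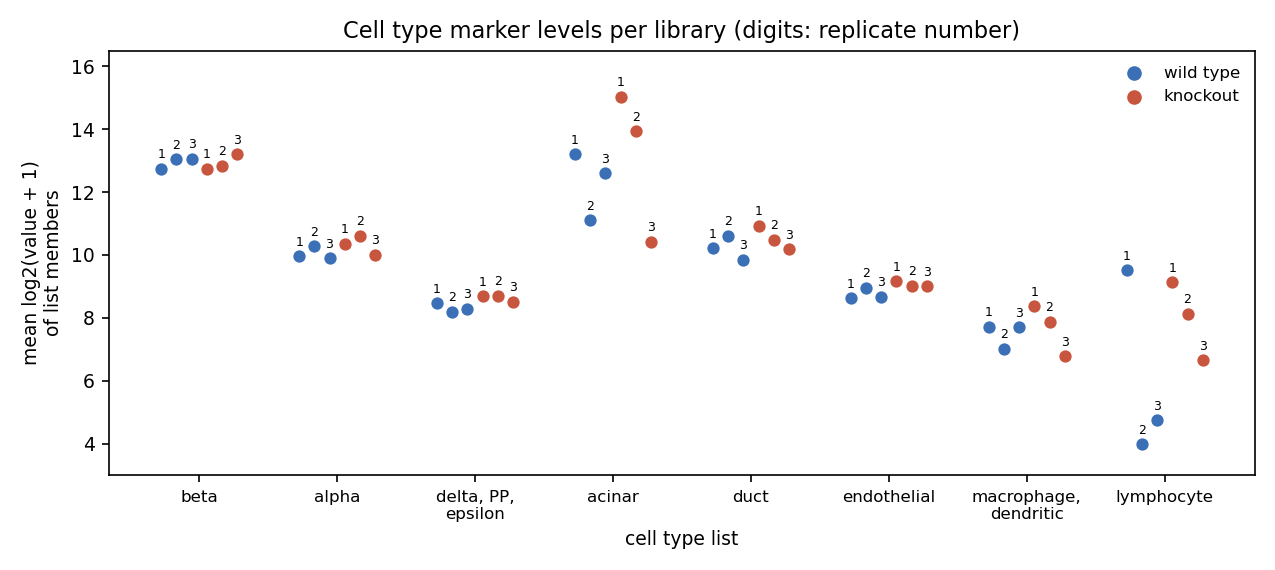
Mean log2(normalized value + 1) of the members of 8 cell type lists (x axis) in each library, with points for wild type (blue) and knockout (red) libraries and digits for the replicate number. The acinar level ranged 24.5-fold and the lymphocyte level 46.3-fold over the 6 libraries, while the beta cell level ranged 1.38-fold.

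Libraries did not group by genotype along the main axis of variation. The first principal component held 48.2% of the variance and placed wild type replicate 1 and knockout replicates 1 and 2 on one side. Lymphocyte genes gave 8 of its 100 most negative loadings, and genes of stellate cells, fibroblasts and extracellular matrix gave 7 of its 100 most positive ones. Genotype accounted for 8.12% of the spread along this component and for 80.1% along component 4, which held 11.2% of the variance. Along components 2, 3 and 5 it was 9.72%, 1.80% and 0.25%. With 6 libraries the components together take up any split in full. A large share along some component is therefore no sign of a genotype axis.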

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

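The lymphocyte covariate and the fit without knockout replicates 1 and 3 were chosen after the data were seen. That fit left 1 knockout library, so its calls rest on how that library differs from wild type. Limma called 0 genes under all 20 of its alternatives. EdgeR called 0 (514 at an unadjusted p under 0.05) and DESeq2 12 (603), and why they differ was not tested. The Sec16b log2 fold change was negative under all 22 alternatives (−1.61 to −1.002, adjusted p 0.0991 to 0.9999), with −1.61 without wild type replicate 2. Camera called 14 lists, 0 with an estimated correlation, and 9 to 21 with a library left out (9 without wild type replicate 3, 21 without knockout replicate 3). The ER chaperone, COPI, endothelial, inflammatory and immediate early lists passed in 22 of 23 alternatives, all but the estimated correlation. Those 22 kept the preset correlation and reused the same libraries, so the count cannot show that the calls hold without that preset. Every split of the libraries into equal groups, the real one included, called between 9 and 17 lists.

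Of 63 other genes under the naming rule, 4 changed sign in 12 of 1369 values and 9 values newly passed. Of 733 list values, 46 lost and 36 gained a call with the direction kept. Another 13 turned direction with a call in at least 1 of the 2 fits, and 56 changed sign in all. Of the 18 lists that did not pass, 14 passed under at least 1 alternative, in 45 values with turned ones counted. With DESeq2 the cell cycle mean was −0.35. With the lymphocyte covariate the means were −0.73 for cell cycle, −0.17 for acinar, −0.15 for integrated stress and 0.0049 for disallowed genes, whose camera direction turned. Without knockout replicates 1 and 3, integrated stress was −0.10 and sterol synthesis 0.34. Leaving out each library gave −0.13 to 2.18 for acinar, −0.056 to 0.75 for interferon, −0.36 to 0.81 for cell cycle, −0.19 to 0.30 for integrated stress, −0.14 to 0.43 for glycolysis and −0.23 to 0.16 for sterol synthesis. The cause was not tested. The acinar list has no value under the acinar covariate, nor the lymphocyte list under its own, since each is that covariate. The first component held 42.8% without a filter and 54.3% with a filter at 50, from other sets of genes. The delta, PP and epsilon level differed by 0.19 as a median, against 0.32 as a mean.

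With the replicate number as a block, limma called 0 genes (864 at an unadjusted p under 0.05) and camera 15 lists. The glycolysis and hypoxia list gained its call there (0.22, camera adjusted p = 0.00934). Residuals of same-numbered libraries correlated at 0.43, 0.0037 and 0.37 for numbers 1, 2 and 3. Libraries numbered 1 and 3 correlated best with their own number, and those numbered 2 did not. So few residuals cannot tell whether the numbers pair the libraries. In simulated data with 3 libraries per group and 200 changed genes per run, 32.0% of 2-fold changes were called, so many were missed there.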

Other observations

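Ribosomal protein genes were higher almost throughout, with 54 of 55 above 0 and a mean log2 fold change of 0.19, and Rps27 at 0.47 (SE 0.17), Rps28 at 0.33 (SE 0.16) and Rps23 at 0.34 (SE 0.20). These genes have many pseudogene copies, so single values are uncertain. Camera gave an adjusted p of 4.0e-07 (adjusted p = 0.857 with an estimated correlation). The mean was 0.04 without knockout replicate 1 and 0.06 without wild type replicate 3, where the call was lost, as it was with the lymphocyte covariate (0.01), and 0.32 without wild type replicate 1 and 0.36 without knockout replicate 3. Of 19 circadian clock genes 15 were higher, with a mean of 0.19, led by the clock repressors Nr1d1 (0.69, SE 0.25) and Nfil3 (0.76, SE 0.30) and by Per1 (0.52, SE 0.22). Camera gave an adjusted p of 0.0290 (adjusted p = 0.594 with an estimated correlation), and the call was lost without wild type replicate 1 (0.22), wild type replicate 2 (0.17) or knockout replicate 1 (0.11). It was also lost with the acinar covariate (0.15, adjusted p = 0.0659) and with the lymphocyte covariate (0.13, adjusted p = 0.0775). So it was without knockout replicates 1 and 3 (0.16), where 1 knockout library was left. The count adjusted over the list alone was 0 for both lists.

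Metabolic lists did not pass camera with all 6 libraries, but some did under alternatives. Oxidative phosphorylation (48 genes) had a mean of −0.02 (adjusted p = 0.405), glycolysis and hypoxia 0.22 (0.108), sterol synthesis −0.04 (0.370), and fatty acid synthesis, storage and oxidation 0.08 with a median of −0.01 (0.750). Autophagy and lysosome genes had −0.04 (0.105), antioxidant genes 0.13 with a median of −0.0029 (0.331), apoptosis and p53 targets 0.11 (0.346), insulin and IGF signalling 0.09 (0.570) and cell cycle genes 0.13 (0.964). Glycolysis and hypoxia passed in 8 of 23 alternatives, among them edgeR (0.30), DESeq2 (0.30) and quantile normalization (0.21) on the higher side, and on the lower side without knockout replicate 1 (−0.14). It also passed without wild type replicate 1 (0.39), knockout replicate 2 (0.37) or knockout replicate 3 (0.43). Sterol synthesis passed in 5, cell cycle in 4, oxidative phosphorylation, autophagy and p53 targets in 2 each, antioxidant genes in 1, and fatty acid genes and insulin signalling in 0. Single libraries moved these means. Sterol synthesis passed without wild type replicate 1 (−0.13), knockout replicate 2 (−0.23) or, on the higher side, knockout replicate 3 (0.16). Cell cycle passed without wild type replicate 1 (0.81) and, on the lower side, without wild type replicate 2 (−0.36). Oxidative phosphorylation ran from −0.061 (without wild type replicate 3, where it passed) to 0.026 (without knockout replicate 2). Autophagy ran from −0.079 (without knockout replicate 1, where it passed) to −0.00023 (without knockout replicate 3). The p53 targets ran from −0.020 (without wild type replicate 3) to 0.25 (without knockout replicate 3, where they passed). Antioxidant genes ran from −0.025 (without knockout replicate 1) to 0.20 (without knockout replicate 3), and passed without knockout replicate 2 (0.20). Fatty acid genes ran from 0.02 (without knockout replicate 2) to 0.18 (without knockout replicate 3), and insulin signalling from 0.03 (without knockout replicate 1) to 0.14 (without knockout replicate 2). The 59 tested genes within 5 Mb of Sec16b on chromosome 1 had a mean of 0.11 (adjusted p = 0.642), with 32 higher and 27 lower. In the lymphocyte list the libraries differed widely, with Ighm at 8441, 59.1 and 310 in wild type and 103162, 5029 and 4447 in knockout replicates 1, 2 and 3.

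Tests of single libraries and of other splits for the list means were chosen after those values were seen, and the spread was added to the single-library tests after their values were seen. The splits for counts and the covariate and scaling tests were written beforehand. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 0 genes with limma (494 at an unadjusted p under 0.05), so each of the 10 splits had to call at least as many, and that count says nothing about chance. The highest other split, wild type replicate 1 with knockout replicates 1 and 2 against the rest, called 135. The first component, computed from the same values, divides the libraries in the same way. The count of 135 is therefore no separate evidence of a structure of the samples. The real split called 14 lists, 5 of 10 splits called as many, and the highest other called 17.

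The lower ER chaperone list is a candidate for follow-up, and a biological explanation, loss of Sec16b, stays open. If acinar cells carried over were the whole cause, the mean of −0.22 should shrink past −0.11 with the acinar level as covariate. It was −0.23 (SE 0.12), beyond that bound by barely more than 1 SE. A gap that small in 6 libraries cannot exclude acinar cells as the whole cause. Under quantile normalization the mean was −0.24, which argues against library scaling as the whole cause. That rests on 1 fit, since the deposited values already carry DESeq2's size factors and median-of-ratios rescaling nearly repeats them. A single library could not be excluded, since the mean was −0.14 (SE 0.09) without wild type replicate 3. Of 10 splits 2 gave a mean as far from 0 (0.22 against a highest other of 0.24), too few splits to exclude chance.

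Higher immediate early genes may follow islet handling or acinar carry-over as much as genotype. With the acinar covariate the mean of 0.67 was 0.45 (SE 0.22), within 1 SE of the bound of 0.34, so acinar cells cannot be told apart from genotype at this number of libraries. Without knockout replicate 1 it was 0.36 (SE 0.41), which leaves a single library open too. Of 10 splits 2 gave a mean as far from 0 (0.67 against a highest other of 0.96), and 10 splits are too few to exclude chance. Handling time was not recorded in the labels and was not tested.

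The lower Sec16b level in the knockout libraries was set against acinar carry-over as well. Acinar cells as the cause of the difference would bring the log2 fold change of −1.22 past −0.61. With the acinar covariate it was −1.21 (SE 0.39), beyond that bound by more than 1 SE. At this number of libraries that argues only weakly against acinar cells. The source of the transcript that persists in the knockout libraries was not tested. Whether the remaining reads may come from a transcript of the disrupted allele cannot be judged from values per gene.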
